A study of Mus musculus with 2 samples.

How the data were processed

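RNA with poly(A) tails was sequenced from 2 biological replicates of ES-Bruce4, a mouse embryonic stem cell line, with 1 library each. The labels number the replicates 1 and 2 and give each its own biosample, so the spread reported is that between 2 cultures of a single line. They give the RNA as longer than 200 bases and the genome as mm10. For each library a table per gene and a table per transcript were deposited, and the README files deposited with them name the mm10 assembly, the GENCODE M4 annotation and alignments to the transcriptome as the origin of the tables. The aligner, the quantifier and the use of strand are not given in the sources used here.

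Per the file headers, the tables hold expected counts, which the authors estimated per gene and per transcript without normalization and which are fractional where a read fits several places. The TPM values as deposited were scaled by the authors over all entries of a file, spike-in sequences included. The FPKM values as deposited were scaled by the authors by effective length and by the reads of the library. Posterior mean estimates of TPM were also deposited, in which entries without reads have values above 0. The isoform percentages (percent of the TPM of a gene taken by each transcript) are as the authors deposited them. Per the file headers, further columns hold the posterior standard deviation of the count, which measures how uncertainly reads were assigned, and the effective length, which was 29 bases below the length in 99.96% of entries.

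Of 43346 gene entries, 42462 were matched by identifier to GENCODE M21 for symbols, classes and coordinates, and 884 were not. Coordinates count from 1. Entries for 96 ERCC spike-ins, for phiX and for 26248 short numbered features were left out of library sizes and of all gene comparisons. Expected counts on genes were 11859255 in replicate 1 and 10620057 in replicate 2. A count of 0 allows up to 3 counts, and binomial intervals and floors cover counting error only. Bootstrap intervals resample genes and cover the spread between them.

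Detection was set at a TPM of at least 1, and a high level at 10, in both replicates. Replicates were compared on log2(TPM + 1) by Pearson's r and Spearman's rho across genes. The biological coefficient of variation was estimated in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr and a design with an intercept alone, on rounded expected counts. TMM factors were 0.997 and 1.003, and DESeq2 1.42.0 size factors 1.05 and 0.950. Ratios of replicate 2 over replicate 1 used TMM-normalised counts with 0.5 added, for genes with a mean of at least 100, and exact binomial 95% intervals. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

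Before the data were examined, 29 gene lists, 16 gene pairs, 5 comparisons between lists, the tests and the alternatives were fixed. The level of a list was the median over its members of the mean log2(TPM + 1), placed among 10000 random lists of protein-coding genes of the same size. The 5 comparisons between lists used two-sided permutation tests of the difference of means with 100000 resamples and Benjamini-Hochberg adjustment at 0.05. Shifts of lists and chromosomes between replicates were medians of the log2 ratio, placed among 10000 random sets matched on expression, with members of a mean normalised count of at least 10 for lists and 100 for chromosomes. Zscan4a and Peg13 had no match and were left out of their lists. Some genes stand in 2 lists.

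The text names every core pluripotency gene. Of each other list it names up to 4 members of highest mean TPM and, for lists with members on both sides of 1 TPM, up to 3 of the lowest. It also names the members of the pairs, the 20 nuclear genes of highest mean TPM, the 10 genes of largest ratio between replicates in each direction, and the isoforms of Pkm, Dnmt3b, Pou5f1, Nanog, Tcf7l1 and Mdm2. Other genes, among them X-linked homologs and members of gene families, were chosen after their values were seen.

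The methods were tested on simulated data. Coefficients of variation of 0.05, 0.1 and 0.3 were recovered as 0.0503, 0.0988 and 0.297. Of unchanged lists 6.5% fell outside the central 95%, and 4.5% of comparisons between unchanged lists passed 0.05. All lists shifted by 0.3 between replicates were found (100%), as were 98% of lists set 4 apart in level. These simulated lists had a single size and a single spread of ratios, and differences in level under 4 were not simulated. Among the real lists, random medians for definitive endoderm ran from -0.36 to 0.32, so a shift of 0.3 could be missed there. At a coefficient of 0.1, 99% of genes changed 3-fold were called 2-fold apart, with 0 unchanged genes called, and at 0.3 the figures were 82% and 1124.

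Alternatives changed 1 choice at a time except where named below: the pseudocount, the detection threshold, filters on low counts, the unit (FPKM, posterior mean TPM, TPM rescaled over nuclear protein-coding genes), DESeq2 in place of edgeR, medians in place of means, other random lists, and each replicate left out. For ratios between replicates, the alternative with TPM as deposited changed the unit, the normalization and the offset (0.1 TPM in place of 0.5 counts) together, and the alternative with DESeq2 gene-wise dispersions changed both the tool and the statistic. A restriction of the ratios between replicates to nuclear protein-coding genes was added after the data were seen. The correlation over nuclear protein-coding genes alone was not part of the fixed design either.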

Results

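RNA with poly(A) tails was measured by sequencing in ES-Bruce4, a mouse embryonic stem cell line that the labels describe as male. The series holds 1 group with 2 biological replicates of the line, each with its own biosample and its own library. No treatment or second cell type was part of the design, so the comparisons below are between genes, between fixed lists of genes and between the 2 replicates. Expected counts, which are read counts estimated per gene and need not be whole, summed to 12060428 in replicate 1 and 10809637 in replicate 2. Of these, 11859255 and 10620057 fell on genes. Levels are in TPM, the abundance of transcripts scaled to the same sum in each library, and values after ± are SDs over the replicates (n = 2) throughout. Coordinates are on mm10.

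Among the 20 nuclear genes of highest mean TPM were genes of translation, protein folding and the cytoskeleton. Eef1a1, the translation elongation factor, was at 13343 ± 840.2 TPM (SD, n = 2). The cytosolic chaperones Hsp90ab1, Hsp90aa1 and Hspa8 were at 4601 ± 84.4, 4579 ± 199 and 3375 ± 0.686 TPM. Ferritin light chain (Ftl1) was at 3988 ± 177, the ribosomal proteins Rplp1 and Rps26 at 3679 ± 85.1 and 3286 ± 163, nucleophosmin (Npm1) at 3149 ± 228, and the actins Actb and Actg1 at 2724 ± 148 and 2471 ± 116 TPM. A gene specific to pluripotent cells stood among these 20 highest nuclear genes: Dppa5a (chromosome 9, 78367052 to 78368177) reached 3175 ± 3.15 TPM. The other 9 of the 20 were short genes, pseudogenes and genes that hold or overlap repeated sequence, for which TPM is a poor guide to abundance. They were Gm42418 and Mir6236 (24929.6 ± 1358 and 22004 ± 3351 TPM), the short genes Gm24270, Gm23935 and Gm24245 with identical values (5419.7 ± 847 TPM each), the mitochondrial-like pseudogenes Gm10925 and Gm10222 on chromosome 1 (5287 ± 480.2 and 3450.0 ± 25.6 TPM), Rpl39-ps (2625 ± 104 TPM) and Lars2 (4008 ± 41.3 TPM). An identifier with no match in the annotation, ENSMUSG00000045999.9, was higher still at 36254 ± 164 TPM. Another without a match, ENSMUSG00000089855.1, was above Eef1a1 at 15560 ± 4232 TPM.

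In all, 15244 genes had a TPM of at least 1 in both replicates, and 12215 of these were protein-coding, out of 21474 protein-coding genes listed. A TPM of at least 10 in both was reached by 8492 genes, 7769 of them protein-coding. Nuclear protein-coding genes took 81.5% of the gene counts in replicate 1 and 81.1% in replicate 2. Across the 17625 genes with a TPM of at least 1 in either replicate, Pearson's r between the replicates was 0.964 and Spearman's rho 0.961 on log2(TPM + 1). Across the 12790 nuclear protein-coding genes among them r was 0.991. These correlations are across genes, which are not independent replicates.

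All 13 core pluripotency genes were expressed above 10 TPM in both replicates. The transcription factors at the centre of the network stood at 376 ± 5.44 TPM for Nanog (chromosome 6, 122707489 to 122714633), 256 ± 10.2 TPM for Pou5f1 (chromosome 17, 35506018 to 35510772) and 250.5 ± 7.42 TPM for Sox2 (chromosome 3, 34650405 to 34652461). Sall4, a zinc finger factor that acts with them, was at 181 ± 4.03, and Zfp281 at 57.1 ± 2.33 TPM. Trim28, the corepressor of KRAB zinc finger proteins, was the highest of the list at 495 ± 9.28. The Nodal co-receptor Tdgf1 was at 256 ± 13.5, the RNA-binding proteins L1td1 and Lin28a at 202 ± 15.4 and 139 ± 12.4, and Utf1 at 154 ± 11.3 TPM. Fgf4, the growth factor that embryonic stem cells secrete, was at 49.5 ± 0.0919. The neighbouring genes Dppa4 and Dppa2 were at 63.1 ± 0.919 and 17.3 ± 4.31 TPM, with expected counts of 331 and 213 for Dppa2.

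The median of the list was 7.51 ± 0.03 on the log2(TPM + 1) scale, above each of 10000 random lists of protein-coding genes of the same size. Set against 56 genes of 5 pooled somatic lists (neural ectoderm, primitive streak and mesoderm, definitive endoderm, blood and endothelium, striated muscle), the mean of the core genes was 5.96 higher on that scale (7.14 against 1.18). The difference was seen in each of the 2 libraries and gave p = 1e-05 in a two-sided permutation test with 100000 resamples, the smallest value these can give, and an adjusted p = 5e-05 over the 5 list comparisons made. This test and the others between lists resample genes, which are not independent replicates, and they describe these cultures of a single line. The lists hold different genes, and no second cell type was measured in which to compare the same genes. A difference between lists is thus one between the genes chosen, and its p-value does not show which state or lineage the cells have.

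**Figure D1:**
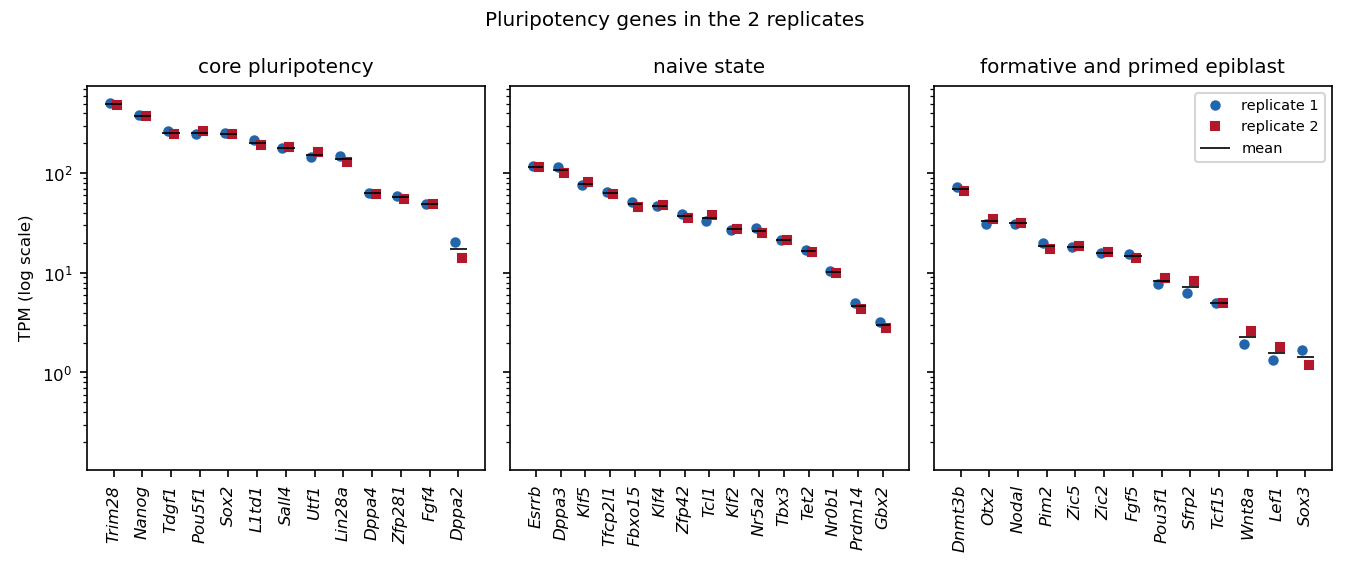
TPM on a log scale of each gene of the core pluripotency, naive state and formative and primed epiblast lists, with blue circles for replicate 1, red squares for replicate 2 and a line at their mean. Trim28 (495 ± 9.28) leads the core list, Esrrb (116 ± 2.55) the naive list and Dnmt3b (70.1 ± 4.37) the formative and primed list.

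Genes of the naive state, the condition of the inner cell mass before implantation, were all 15 above 1 TPM, and 12 were above 10 TPM in both replicates. The nuclear receptor Esrrb was at 116 ± 2.55 TPM (n = 2), Dppa3, a maternal factor that guards DNA methylation, at 107 ± 10.3, and the transcription factors Klf5 and Tfcp2l1 at 78.7 ± 3.45 and 63.4 ± 1.58 TPM. Genes of the formative and primed epiblast were also all present above 1 TPM: the de novo DNA methyltransferase Dnmt3b was at 70.1 ± 4.37, Otx2 at 32.9 ± 2.47, the ligand Nodal at 31.4 ± 0.191 and the kinase Pim2 at 18.5 ± 1.81 TPM. Fgf5, a classical marker of the epiblast after implantation, was at 14.8 ± 0.940 TPM. Zfp42 (Rex1), which marks the naive state, stood 1.33 ± 0.02 above Fgf5 on the log2 scale, a 2.52-fold ratio. Klf4 (47.4 ± 0.410 TPM) was 1.74-fold higher than Klf2 (27.3 ± 0.587), and Lefty2 (76.9 ± 3.26), a feedback inhibitor of Nodal, 2.45-fold higher than Nodal. The mean of the naive list exceeded that of the formative and primed list by 1.38 on the log2(TPM + 1) scale (4.92 against 3.54), in each of the 2 libraries, with p = 0.021 and an adjusted p = 0.026 (two-sided permutation test). Compared by medians the difference was 1.21 with an adjusted p = 0.061 in the same permutation test, and over the alternatives tried the adjusted p ranged from 0.022 to 0.061. Their list medians were 5.19 ± 0.06, at percentile 99.9 of the random lists, and 3.98 ± 0.09, at percentile 93.0. As the lists hold different genes, the difference of their means does not by itself tell a naive from a primed state.

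Genes of the two-cell-like state, a rare state in embryonic stem cell cultures, were close to the limit of detection. Zscan4f was at 1.25 ± 0.0212 TPM (expected counts of 11.1 and 6.93) and was the 1 member of 11 above 1 TPM in both replicates. Zscan4e and Zscan4b were at 0.195 ± 0.276 and 0.135 ± 0.191 TPM, and Usp17lc at 0.160 ± 0.0566 TPM. No counts were assigned in either library to Tcstv1, Tdpoz4 or Duxf3, the mouse Dux gene, which allows up to 3 counts of each per library. The list median was 0.11, at percentile 4.37 of the random lists. None of the 29 lists lay at or below percentile 2.5, whereas with replicate 1 alone or replicate 2 alone 1 list did, and against random lists drawn from genes with a TPM of at least 1, 9 lists did. The Zscan4 genes are near-identical copies, so the division of reads among them is uncertain.

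Of 13 genes of the germ line and of meiosis, 9 were above 1 TPM in both replicates, and Tex19.1 (16.8 ± 0.849 TPM), which acts in transposon control, was above 10 TPM. Dmc1, the meiotic recombinase, was at 9.96 ± 0.247, the RNA helicase Ddx4 at 9.36 ± 0.304 and the chromosome axis protein Sycp3 at 6.56 ± 3.0 TPM. Stra8, Brdt and Asz1 were at 0.535 ± 0.163, 0.510 ± 0.0990 and 0.130 ± 0.0707 TPM. The mean of the list was 0.67 above the pooled somatic lists (1.85 against 1.18), in each of the 2 libraries, which did not pass the test (p = 0.12, adjusted p = 0.12, two-sided permutation test). With a pseudocount of 0.1 the difference was 1.44 with an adjusted p = 0.045 in the same permutation test, and over the alternatives the adjusted p ranged from 0.045 to 0.16. The list median was 1.67 ± 0.32, at percentile 43.3.

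Most markers of each somatic lineage did not reach 1 TPM in both replicates. In neural ectoderm, 4 of 13 genes were above 1 TPM in both replicates: the intermediate filament Nes (20.9 ± 0.318 TPM), the transcription factor Olig2 (16.2 ± 0.728), the tubulin Tubb3 (11.8 ± 0.403) and Pax3 (2.15 ± 0.276). Neurog2, Ascl1 and Fabp7 had no counts in either library, which allows up to 3 counts each. In primitive streak and mesoderm, 5 of 13 were above 1 TPM, led by Fgf8 (14.2 ± 1.44 TPM), the T-box factor T (brachyury, 10.4 ± 0.834), Wnt3 (7.11 ± 1.24) and Eomes (5.49 ± 0.177), while Msgn1, Foxf1 and Mesp1 were at 0.120 ± 0.170, 0.10 ± 0.0707 and 0.0950 ± 0.00707 TPM. In definitive endoderm, 4 of 10 were above 1 TPM. Trh, the precursor of thyrotropin-releasing hormone, was far above the rest at 92.7 ± 6.72 TPM, with Hhex, Cer1 and Cxcr4 at 4.17 ± 0.0707, 2.79 ± 0.240 and 2.75 ± 0.134, and Hnf1b, Pyy and Nepn at 0.230 ± 0.0141, 0.130 ± 0.184 and 0.0350 ± 0.0495 TPM. Of the blood and endothelium genes, 4 of 10 were above 1 TPM, with Gata1 at 3.37 ± 0.396, Tek at 2.82 ± 0.665, Runx1 at 2.10 ± 0.0707 and the globin Hba-a1 at 1.23 ± 0.255 TPM, which has a near-identical copy. Cdh5, Tie1 and the leukocyte antigen Ptprc were at 0.220 ± 0.0141, 0.155 ± 0.0354 and 0.105 ± 0.120 TPM. In striated muscle, desmin (Des) was at 14.3 ± 2.53 TPM and Myh7 at 1.42 ± 0.0283, these being the 2 of 10 above 1 TPM in both, with Actc1 at 1.28 ± 0.629, Tnnt2 at 0.925 ± 0.332, Nkx2-5 at 0.0800 ± 0.113, Myog at 0.0400 ± 0.0566 and Myod1 without counts. The medians were 0.33 ± 0.06, 0.52 ± 0.09, 0.75 ± 0.01, 0.47 ± 0.24 and 0.50 ± 0.16 in that order, at percentiles 9.56, 15.3, 19.8, 13.7 and 14.9 of the random lists.

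Extracellular matrix genes were the highest members of the extraembryonic endoderm list. Among 15 genes of primitive and extraembryonic endoderm, Sparc was at 327 ± 13.7 TPM (n = 2), the laminin chain Lamb1 at 104 ± 7.42 and the basement membrane collagens Col4a2 and Col4a1 at 26.5 ± 2.25 and 20.8 ± 0.0283 TPM. Afp, Hnf4a and Ttr, secreted proteins and a regulator of later visceral endoderm, were at 0.0300 ± 0.0424, 0.0150 ± 0.0212 and 0 TPM. The transcription factors Gata4, Sox7 and Gata6 were at 2.77 ± 1.23, 0.710 ± 0.170 and 0.520 ± 0.156 TPM, and the receptor Pdgfra at 0.760 ± 0.354. Dab2 (20.7 ± 0.629 TPM) and Lama1 (9.81 ± 0) were higher, and all of these were named after their values were seen. In all, 7 members were above 1 TPM in both replicates and 7 below 1 in both. The mean of the list was 1.31 above the pooled somatic lists (2.49 against 1.18), in each of the 2 libraries, with p = 0.012 and an adjusted p = 0.02 (two-sided permutation test). By medians the difference was 0.40, with an adjusted p = 0.33 in the same permutation test, and over the alternatives the adjusted p ranged from 0.016 to 0.33. The list median was 0.89 ± 0.04, at percentile 23.2.

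Genes of fibroblasts, on which embryonic stem cells are often grown, were mostly detected: 14 of 17 were above 1 TPM in both replicates. Fibronectin (Fn1) was at 492 ± 15 TPM, the smooth muscle protein Tagln at 93.5 ± 6.85, vimentin (Vim) at 56.5 ± 2.14 and Acta2 at 24.4 ± 4.95 TPM. Twist2, decorin (Dcn) and lumican (Lum), the lowest of the list, were at 1.15 ± 0.806, 0.960 ± 0.127 and 0.270 ± 0.113 TPM. Between these and the highest stood Col1a1 at 16.2 ± 4.12 and Thy1 at 3.88 ± 0.283 TPM, both named after their values were seen. The mean of the list was 1.90 above the pooled somatic lists (3.08 against 1.18), in each of the 2 libraries, with p = 0.0002 and an adjusted p = 0.0005 (two-sided permutation test). The list median was 2.29 ± 0.08, at percentile 57.0 of random lists. The difference is between different genes, so it does not show whether feeder cells were present, which was not tested.

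Among 14 trophectoderm genes, the simple epithelial keratins Krt18 and Krt8 were at 208 ± 3.32 and 199 ± 1.89 TPM, Fgfr2 at 25.3 ± 1.94 and Krt7 at 21.2 ± 2.28 TPM. The transcription factors Cdx2 and Elf5 were at 0.525 ± 0.148 and 0.215 ± 0.0212, and the placental hormone gene Prl3d1 had no counts. Other transcription factors of the list, named after their values were seen, were higher, with Tead4 at 20.3 ± 1.90 and Gata3 at 6.63 ± 1.00 TPM. The list had 11 members above 1 TPM in both replicates and a median of 2.96 ± 0.19, at percentile 74.2.

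**Figure D2:**
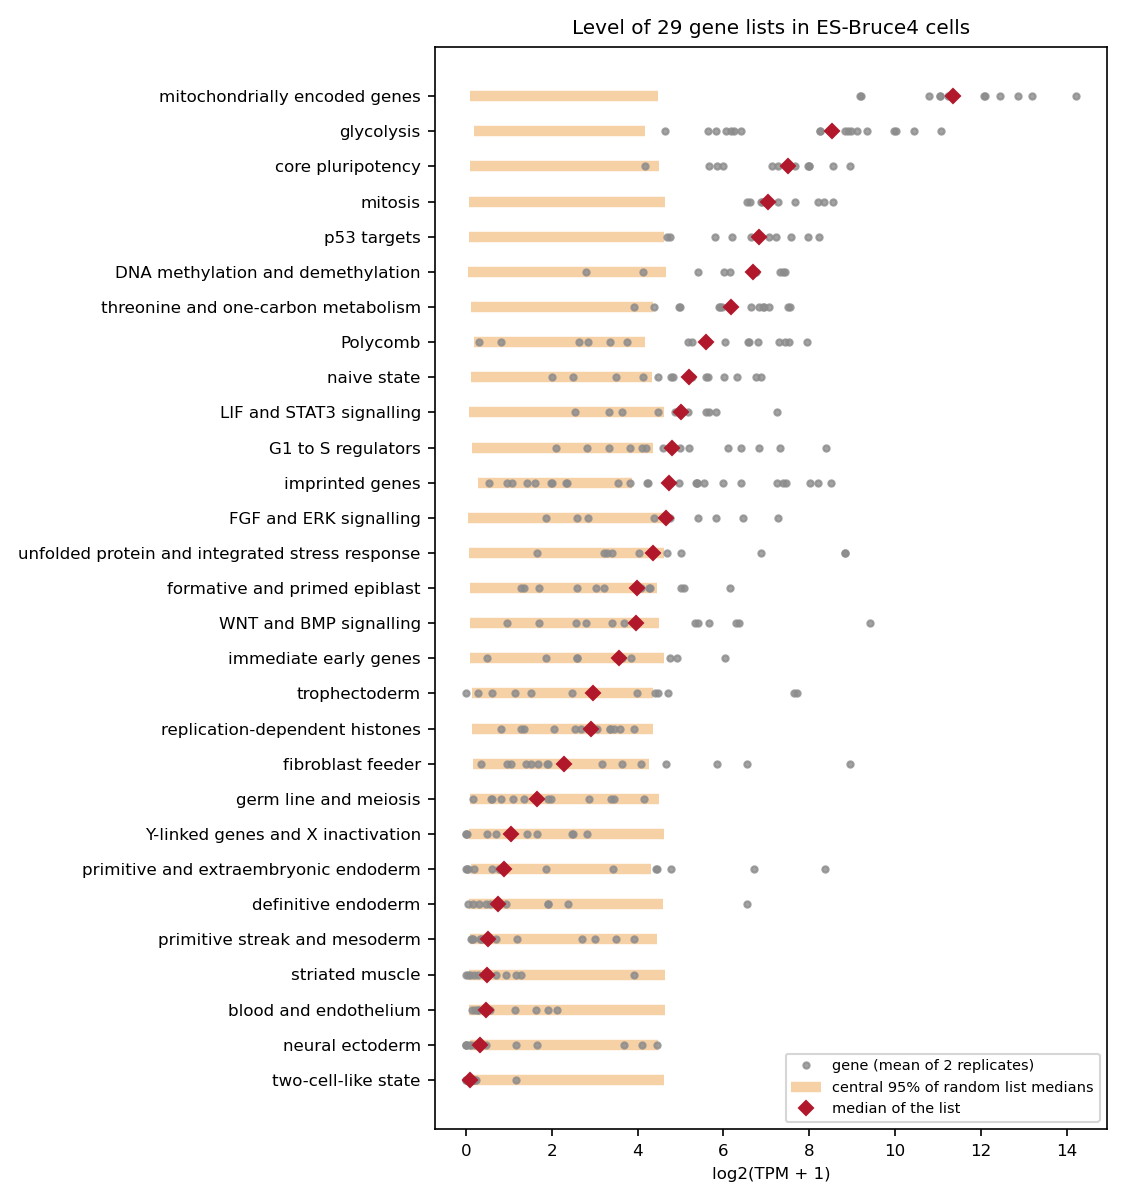
Level of each gene of the 29 fixed lists as the mean of 2 replicates (grey points), on the log2(TPM + 1) scale, with the list median (red diamond) and the central 95% of medians of random lists of protein-coding genes of the same size (orange bar). List medians run from 0.11 for the two-cell-like state to 11.35 for the mitochondrially encoded genes, and 13 of the red diamonds lie at or above the upper end of their bar, against 12 with random lists matched on length and 10 with random lists from genes with a TPM of at least 1.

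The signalling pathways that govern self-renewal were represented by receptors, transducers and targets. All 10 genes of the LIF and STAT3 list were above 1 TPM and 8 above 10 TPM, led by the kinases Pim1 (152 ± 5.37 TPM), Jak1 (56.2 ± 3.45) and Pim3 (49.4 ± 2.98) and by the shared receptor Il6st (47.2 ± 2.36). All 11 genes of the FGF and ERK list were above 1 TPM, with the ETS factor Etv5 at 155 ± 2.86, the receptor Fgfr1 at 87.1 ± 3.85, the adaptor Grb2 at 56.0 ± 2.02 and the inhibitor Spry2 at 41.8 ± 0.120 TPM. In the WNT and BMP list, 12 of 13 were above 1 TPM: beta-catenin (Ctnnb1) was at 682 ± 17.3, the receptor Bmpr1a at 81.5 ± 0.799, and the factors Tcf7l1 and Tcf7 at 77.7 ± 3.61 and 49.6 ± 4.02 TPM. The WNT targets Sp5, Cdx1 and Nkd1 were at 4.91 ± 0.332, 2.29 ± 0.339 and 0.95 ± 0.156 TPM. Of the immediate early genes, Btg2, Dusp1, Ier2 and Nr4a1 were at 65.2 ± 0.332, 29.3 ± 0.820, 25.9 ± 0.502 and 13.3 ± 1.03 TPM, whereas Atf3, Egr1 and Fosb were at 5.03 ± 0.728, 2.63 ± 0.177 and 0.425 ± 0.205 TPM. List medians were 5.02 ± 0.09, 4.66 ± 0.05, 3.96 ± 0.16 and 3.56 ± 0.03, at percentiles 99.2, 97.9, 92.4 and 83.9 of the random lists.

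Regulators of DNA methylation were all above 1 TPM, and 10 of 11 above 10 TPM. Zfp57, which protects imprints, was at 173 ± 8.71, the dioxygenase Tet1 at 166 ± 4.05 and Uhrf1, which recruits the maintenance methyltransferase, at 158 ± 2.82 TPM. Tet1 exceeded Tet3 (5.92 ± 0.262 TPM) 28.0-fold, a log2 ratio of 4.81 ± 0.10 (n = 2). Dnmt3b exceeded Dnmt3a (41.2 ± 0.672 TPM) 1.70-fold (0.77 ± 0.11). Polycomb genes were led by Suz12 (248 ± 28.0 TPM), Jarid2 (184 ± 15.1), Mtf2 (173 ± 22.2) and the methyltransferase Ezh2 (157 ± 0.445), with 16 of 18 above 1 TPM. Bmi1 was at 5.26 ± 1.22, and Cbx8 and Cbx4 at 0.775 ± 0.375 and 0.235 ± 0.0778 TPM. Within families, Ezh2 was 4.18-fold above Ezh1 (37.6 ± 2.85), and Cbx7 (64.7 ± 0.318 TPM) 6.94-fold above Cbx2 (9.35 ± 0.813). Both lists had medians above each of the 10000 random lists, 6.70 ± 0.07 and 5.60 ± 0.02.

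The pairs of alternative subunits of the BAF chromatin remodelling complex were unequal. The ATPase Smarca4 (67.7 ± 4.29 TPM) was 30.7-fold above Smarca2 (2.21 ± 0.240), and Smarcc1 (100.5 ± 2.54 TPM) 9.17-fold above Smarcc2 (11 ± 0.785), with log2 ratios of 4.94 ± 0.25 and 3.20 ± 0.14. Actl6a was at 94.5 ± 8.17 TPM, and the neuronal Actl6b had 2 counts in replicate 1 and 0 in replicate 2, too few for a ratio. The RNA-binding protein Lin28a exceeded Lin28b (11.8 ± 1.43 TPM) 11.8-fold, and Mycn (45.0 ± 0.940 TPM) exceeded Myc (9.10 ± 0.651) 4.95-fold. Of the 16 gene pairs fixed in advance, the first member was higher in both replicates in 13, a count that depends on the order chosen within the pairs. Each of the 15 log2 ratios that could be formed was larger in size than its SD.

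Imprinted genes included several of high level. Peg10, a gene derived from a retrotransposon, was at 366 ± 7.86 TPM, the noncoding RNA H19 at 292 ± 1.46, Gnas at 258 ± 12.2 and the growth factor Igf2 at 176 ± 0.665 TPM. Rtl1, Usp29 and Magel2 were at 1.11 ± 0.0707, 0.970 ± 0.311 and 0.460 ± 0.141 TPM. Of 27 imprinted genes matched, 25 were above 1 TPM in both replicates and 18 above 10 TPM, and the median of 4.73 ± 0.11 stood at percentile 99.97 of the random lists. Use of strand in the counting is not given in the sources used here, so values of genes with transcription from the opposite strand may include reads of both. The values give no information on which parental allele was transcribed.

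Transcripts of the Y chromosome were detected at low levels in this line labelled male. Eif2s3y was at 6.54 ± 3.64 TPM, Uty at 4.68 ± 0.368 and Ddx3y at 2.19 ± 0.70 TPM, with expected counts of 99.4 and 61.3, 93.3 and 86.1, and 77.7 and 47.2 in replicates 1 and 2. Usp9y was at 0.0150 ± 0.00707 TPM with 1 count in each library, and Zfy2 and the testis-determining gene Sry had none, which allows up to 3 counts each. Zfy2 had posterior SDs of 2.09 and 1.5 counts in replicates 1 and 2, so reads that fit it may have been assigned elsewhere. Xist, the noncoding RNA of X inactivation, was at 4.58 ± 0.467 TPM, and overlaps the antisense gene Tsix, so without knowledge of strand its value may include reads of Tsix. The list median was 1.06 ± 0.01, at percentile 27.9.

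Messages of glycolysis were among the most abundant in the cells. All 19 genes were above 10 TPM in both replicates: enolase (Eno1) was at 2144 ± 65.7 TPM, the glucose transporter Slc2a3 at 1397 ± 67.8, aldolase (Aldoa) at 1037 ± 18.8 and pyruvate kinase (Pkm) at 1006 ± 52.3 TPM. Slc2a3 exceeded Slc2a1 (498 ± 12.7 TPM) 2.80-fold. Lactate dehydrogenase A (Ldha, 553 ± 37.7 TPM) and B (Ldhb, 454 ± 9.67) differed by a mean of 1.21-fold (log2 ratio 0.28 ± 0.13), and Hk1 (65.6 ± 1.14 TPM) was 1.18-fold above Hk2 (55.8 ± 0.453). The list for threonine and one-carbon metabolism was likewise above 10 TPM in all 15 members, with the serine synthesis enzymes Psat1 and Phgdh at 185 ± 9.03 and 122 ± 2.52 TPM, threonine dehydrogenase (Tdh), on which mouse embryonic stem cells depend, at 179 ± 1.61, and Shmt1 at 134 ± 9.10. The 13 mitochondrially encoded protein-coding genes took 4.47% and 4.44% of gene counts, from mt-Co1 at 19202 ± 1144 TPM to mt-Nd3 at 576 ± 1.41 TPM. The assignment of reads to mt-Nd3 was uncertain, with a posterior SD of 384 on 1563 expected counts in replicate 1 and 227 on 1432 in replicate 2, and mt-Nd4l, mt-Atp6, mt-Co3 and mt-Co2 also had reads of uncertain assignment. The pseudogene Gm10925 held 30988 and 25046 expected counts, against 23008 and 22398 for mt-Atp6. Their posterior SDs were nearly equal (3085 and 3808 counts for each). Gm10222 held 7798 and 7094 expected counts, against 1415 and 1157 for mt-Nd4l. The share of the 13 genes may therefore leave out reads that were assigned to such pseudogenes. The medians of the lists were 8.53 ± 0.07, 6.18 ± 0.05 and 11.35 ± 0.10, each above all random lists.

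Messages of proliferation were high throughout the mitosis list, whose 11 genes all exceeded 10 TPM. Cyclin B1 (Ccnb1) was at 378 ± 30.9 TPM, topoisomerase Top2a at 322 ± 25.4, Cdk1 at 293 ± 11.6 and cyclin A2 (Ccna2) at 202 ± 10.8 TPM. Of the regulators of G1 and S phase, Cdk4 was at 337 ± 12.7, cyclin D3 (Ccnd3) at 159 ± 2.98, the inhibitor Cdkn1a at 112 ± 1.11 and cyclin E1 (Ccne1) at 84.1 ± 7.12 TPM. Ccnd1 (31.0 ± 1.58 TPM) was 9.35-fold above Ccnd2 (3.32 ± 0.226). The p53 list, which includes Trp53 itself (148 ± 17.6 TPM), had all 11 genes above 10 TPM, with Mdm2 at 301 ± 0.594, Trp53inp1 at 249.7 ± 9.58 and Ccng1 at 190.5 ± 7.42. Stress response genes were led by asparagine synthetase (Asns, 457 ± 13.7 TPM), the chaperone Hspa5 (456 ± 11.3), Atf4 (116 ± 0.559) and Xbp1 (31.3 ± 2.78). Replication-dependent histones, whose messages lack a poly(A) tail, had 12 of 14 members above 1 TPM in both replicates, with Hist1h4b, Hist1h1d, Hist2h3b and Hist1h4d at 14.1 ± 0.339, 11.1 ± 0.544, 9.90 ± 0.410 and 9.37 ± 1.44 TPM, and Hist1h4a, Hist1h3b and Hist2h2ab at 1.55 ± 0.226, 1.52 ± 0.877 and 0.760 ± 0.0141 TPM, values made uncertain by near-identical copies. Medians were 7.05 ± 0.01 for mitosis, 4.80 ± 0.03 for G1 to S, 6.82 ± 0.01 for p53, 4.36 ± 0.17 for stress and 2.91 ± 0.10 for histones, at percentiles 100, 99.4, 100, 95.5 and 72.9.

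Transcript tables of the same libraries gave the share of each isoform within its gene. Pkm transcripts with the exon of the M2 type (chromosome 9, 59675568 to 59675734) made up 94.6 ± 0.375% (SD, n = 2) of the gene, and those with the alternative exon of the M1 type (59675029 to 59675195) 5.42 ± 0.375%. Pou5f1-201 held 90.2 ± 0.622% of Pou5f1, and Nanog was divided between Nanog-201 (62.2 ± 5.07%) and Nanog-203 (37.5 ± 4.53%). Of Dnmt3b, Dnmt3b-207 held 39.2 ± 0.339% and Dnmt3b-204 27.2 ± 9.58%. The short Tcf7l1-204 held 46.6 ± 1.63% of Tcf7l1 and the longer Tcf7l1-201 36.4 ± 0.898%. For Mdm2, the leading transcripts Mdm2-206 (22.1 ± 0.304%) and Mdm2-207 (20.9 ± 1.67%) are annotated as non-coding, and the coding Mdm2-202 and Mdm2-201 held 7.62 ± 2.80% and 6.33 ± 5.16%, with Mdm2-202 higher in replicate 1 and Mdm2-201 in replicate 2. Among 6136 genes with at least 2 transcripts and a TPM of at least 10 in both replicates, the top transcript was the same in both for 4830 (78.7%), and its median share was 43.2%. Shares are of TPM, in which a short transcript takes a large share with few reads, as the 132 and 123 expected counts of Tcf7l1-204 show beside 686 and 698 of Tcf7l1-201. The shares rest on 2 libraries and were not tested.

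Between the replicates, 27 of 9896 genes with a mean normalised count of at least 100 differed by a factor of at least 2, 13 higher and 14 lower in replicate 2. Pseudogenes made up 19 of them, out of 340 tested, and small RNAs 5, out of 24, all of these higher in replicate 2. Of 9293 nuclear protein-coding genes, Gm6169 and Eno1b were among the 27, Eno1b being named after its value was seen. The assignment of reads to both was uncertain. Their posterior SD in replicates 1 and 2 was 0.23 and 0.96 of the count for Gm6169 and 0.33 and 0.19 for Eno1b. The log2 ratio of replicate 2 over replicate 1 was -3.07 (95% interval -3.37 to -2.78) for Rpl17-ps5, -2.74 (95% interval -3.09 to -2.41) for Gm4963, -2.61 (95% interval -3.06 to -2.21) for Gm4735 and -2.59 (95% interval -3.15 to -2.11) for Gm6169. It was -2.48 for Rps6-ps4, -1.89 for Gm28661, -1.57 for Gm2423, -1.52 for Gm28437, -1.35 for Gm9083 and -1.33 for Pcna-ps2. In the other direction, Gm6768 had no counts in replicate 1 and 299 normalised counts in replicate 2, Tubb4b-ps1 was at 3.78 (95% interval 3.28 to 4.32) and Gm10243 at 2.26 (95% interval 2.03 to 2.49). The small RNAs Gm22988, Snord100 and Snord14c were at 1.47 (95% interval 1.16 to 1.79), 1.28 (95% interval 0.93 to 1.65) and 1.26 (95% interval 1.08 to 1.45), and Rpsa-ps4, Gm26619, Gm12191 and Gm11572 at 1.47, 1.39, 1.28 and 1.23. With 1 library on each side these differences have no replicate check, and the exact intervals cover counting error only. At a mean count of at least 30 the number was 107, and at 300 it was 13.

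**Figure D3:**
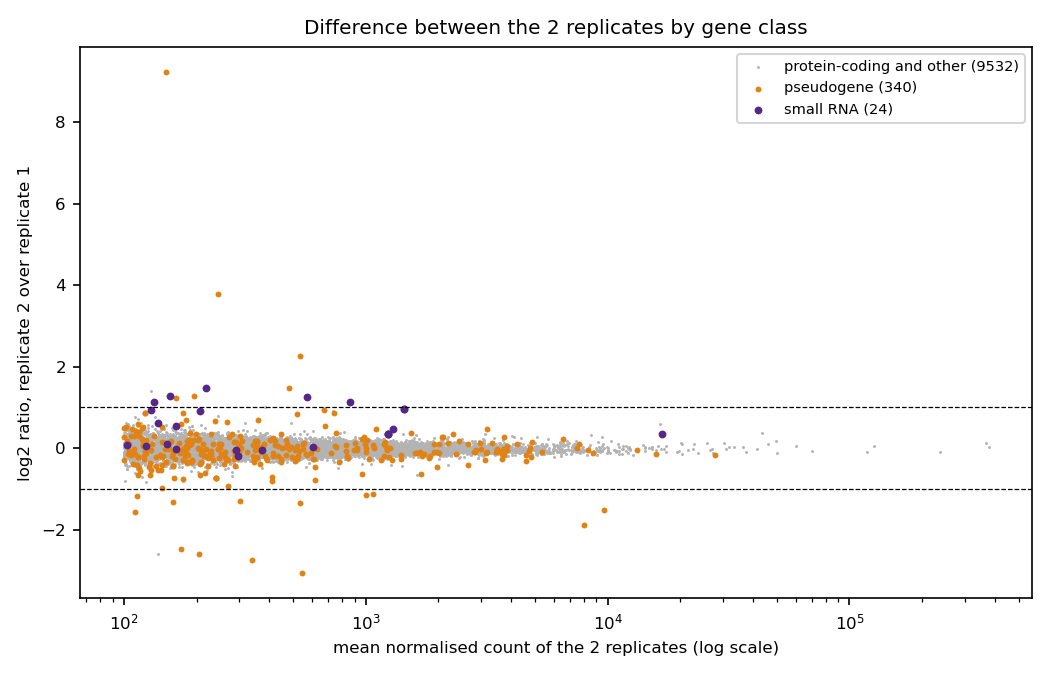
Log2 ratio of replicate 2 over replicate 1 against the mean normalised count (log scale) for the 9896 genes with a mean count of at least 100, with pseudogenes in orange, small RNAs in purple and all others in grey, and dashed lines at a ratio of 2 in each direction. Of the 27 genes at or beyond the lines, 19 are pseudogenes and 5 are small RNAs.

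Of 28 gene lists with enough counts, 3 had a median shift between the replicates outside the central 95% of 10000 random lists matched on expression, where 1.4 would be expected by chance. The WNT and BMP list was 0.16 higher in replicate 2 on the log2 scale, with 10 of 13 genes higher (percentile 99.8), and the p53 list 0.07 higher, with 8 of 11 (percentile 99.2). The list of Y-linked genes and X inactivation was at -0.31, with 2 of 6 higher (percentile 0.77). With TPM in place of normalised counts, and an offset of 0.1 TPM in place of 0.5 counts, 1 list, WNT and BMP at 0.13, was outside the range, and the percentiles were 91.3 for the p53 list and 10.1 for the list of Y-linked genes and X inactivation. With members of a mean normalised count of at least 100, 2 of 23 lists were outside the range: WNT and BMP at 0.09, with 6 of 8 genes higher (percentile 98.5), and p53 at 0.07, with 8 of 11 (percentile 99.1), and the list of Y-linked genes and X inactivation had too few such members for a value. By chromosome, medians of autosomes and X lay between -0.050 (X) and 0.028 (chromosome 17), and 11 of 20 were outside the central 95% of random gene sets. The largest of these medians was 0.050 in size, and the number of chromosomes in the cultures was not tested. The spread between the replicates beyond counting error, as edgeR's biological coefficient of variation over 15125 genes, was 0.0607. The square root of the median DESeq2 gene-wise dispersion was 0.0001. That value is set by the lowest dispersion the tool gives, so it does not measure the spread. By edgeR the coefficient was 0.117 in the lowest of 4 equal groups of genes by expression and 0.0519 in the highest. Over 15813 genes the chi-square of the counts averaged 3.96 per gene with a median of 0.814, where 0.455 is the median for counting error alone.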

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

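No test chosen after the result was seen is reported here. Sequences outside the gene comparisons held reads in both libraries, above the level that a count of 0 allows, which shows that such reads were present and nothing on their source. The ERCC spike-ins, synthetic RNAs that the labels list as used, took 0.0066% of counts in replicate 1 and 0.00639% in replicate 2. The genome of the phage phiX, which is commonly added to sequencing runs as a control, took 1.63% and 1.71%. The short numbered features took 0.032% and 0.0353%. The highest level that a count of 0 allows was 2.49e-05% in replicate 1 and 2.78e-05% in replicate 2. There were no control samples, and no biological explanation was tested.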

How the results depend on the processing

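The restriction of the ratios between replicates to nuclear protein-coding genes was the 1 alternative chosen after the result was seen. The correlation over those genes alone was also outside the fixed design. No difference between lists and no ratio within a gene pair changed direction under the alternatives run for them. Of the median shifts of lists between the replicates, 7 of 28 changed sign with TPM as deposited, 2 of 23 with a mean normalised count of at least 100 and 0 of 28 with DESeq2 size factors. None of the shifts that changed sign lay outside the central 95% of random lists, under either setting. With TPM as deposited the random medians moved down too, so such a change of sign need not be a reversal against other genes. The imprinted genes went from 0.029 (percentile 91.3) to -0.003 (percentile 86.1), whereas blood and endothelium went from percentile 86.0 to 43.0. The differences of core pluripotency and fibroblast genes from the pooled somatic lists kept their side of the threshold under all 6 alternatives each.

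With medians over members, the naive state minus formative and primed epiblast difference was 1.21 and the extraembryonic endoderm minus somatic difference 0.40, and neither passed, so that 2 of the 5 differences passed instead of 4. With a pseudocount of 0.1 the germ line minus somatic difference was 1.44 and passed. The cause was not tested in these cases.

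The correlation between replicates was 0.886 with a pseudocount of 0.1, 0.985 without a filter and 0.992 from TMM-normalised counts. From DESeq2 gene-wise dispersions, the square root of the median over genes was 0.0001, which is set by the lowest dispersion the tool gives. Genes 2-fold apart numbered 107 at a mean count of at least 30, 13 at 300 and 2 among nuclear protein-coding genes, which are different sets of genes by construction. At or below percentile 2.5 there was 1 list with posterior mean TPM, and 9 with random lists drawn from genes of TPM of at least 1. Leaving out a replicate gave 1 list in each case, the lowest and the highest being both 1. With TPM as deposited, which also changed the offset, 1 list shift lay outside the central 95%. With a gene TPM of at least 30, the top transcript was the same in both replicates for 82.8% of genes. The cause was not tested.

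Among single values, TPM of named genes moved by more than the SD of the replicates in 168 of the alternatives and by less in 573. List medians moved in 100 and did not in 74, and ratios within pairs moved in 4 and did not in 41. FPKM and rescaled TPM multiply all genes of a library by the same factor, so they move list medians by construction. No paired analysis was possible because the series holds 1 group. Genes with few counts, such as the Zscan4 family, are limited by depth.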

Other observations

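All tests in this part were chosen after the results were seen, and no biological explanation was tested, since the design holds 1 group. Transcripts of Y-linked genes were far below those of their X-linked homologs. Uty stood at 21.4 ± 2.10% of Kdm6a, Eif2s3y at 3.75 ± 1.99% of Eif2s3x, Kdm5d at 1.55 ± 0.206% of Kdm5c and Ddx3y at 0.622 ± 0.173% of Ddx3x (SD, n = 2). Reads shared between the homologs are argued against by a median relative posterior SD of the 4 Y-linked genes of 1.84%. Loss of the Y chromosome from most cells may contribute. The ratios, of which the highest was 21.4%, are unequal, and without male cells that kept the Y they decide nothing.

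Pseudogenes made up 19 of the 27 genes more than 2-fold apart between the replicates, and their median relative posterior SD was 21.4%, against 4.32 to 8.90% in the central 95% of random sets of the other 321 pseudogenes matched on expression. Reads shared between near-identical copies are a candidate explanation. The ratio lay within 2 combined SDs of posterior and counting error for 3 of the 19, so shared reads as measured by that SD leave most of the size open. The posterior SDs of Gm28661 nearly equalled those of mt-Co2 (1119.92 and 1013.9 against 1119.83 and 1012.48 counts). Those of Gm28437 nearly equalled those of mt-Co3 (8024.76 and 4661.76 against 8024.77 and 4661.71). Both mitochondrial genes were higher in replicate 2 (log2 ratios 0.19 and 0.11), and both pseudogenes lower (-1.89 and -1.52). Reads shared with the mitochondrial gene would give such values for both.

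With genes of identical counts taken once, which leaves 21 of 24, small RNAs were higher in replicate 2 for 17, with a median log2 ratio of 0.47 (bootstrap interval 0.08 to 0.93). Reads shared between copies are argued against as the whole cause, since the 19 with a relative posterior SD below 10% had a median of 0.47 with a lower bootstrap bound of 0.05 (0.0463), and they stay open for the other 2, each standing for genes of identical counts, with an SD above 30%. A difference in the selection of RNA or insert length may contribute: the trend with length among protein-coding genes predicted 0.07 (0.0667) at the length of the small RNAs, of the right sign and below the lower bound of 0.0751. A larger carry-over of RNA without a poly(A) tail was left open too, since the histone median of -0.02 had an upper bound of 0.18 (0.176), inside that interval. The small RNA entries had a median length of 102 bases, shorter than the RNA the labels describe. Whether their reads came from small RNAs or from longer transcripts was not tested. Snord14c (chromosome 9, 40803583 to 40803668) and Snord14d (40803995 to 40804080) lie within Hspa8 (40800984 to 40810087), so they may not be independent. The bootstrap treats the entries as independent and covers no spread between libraries.

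Some gene families were examined after their values were seen. Of 39 Hox genes, 2 were above 1 TPM in both replicates, and of 1050 olfactory receptor genes 2 were. Zfp genes numbered 394, of which 349 were above 1 TPM and 139 above 10. Of 34 Rhox genes 3 were above 10 TPM, and of 53 keratin genes 5 were. The 76 cytosolic ribosomal protein genes took 7.55% of TPM in replicate 1 and 7.59% in replicate 2, and 73 were above 10 TPM. Rhox genes and ribosomal proteins have near-identical copies, so their values are uncertain.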
